A study of Mus musculus with 6 samples.

How the data were processed

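RNA from mouse embryonic stem cells carrying floxed Dicer alleles was measured on 6 Affymetrix arrays. The labels place 3 arrays in a group of untreated cells and 3 in a group of cells given tamoxifen. The labels' protocols describe 3 days with tamoxifen and collection 2 days later, on day 5. They also mention wild-type cells given tamoxifen; arrays of such cells were not analysed here. The labels number the samples 1 to 3 within each group and do not say whether the samples came from separate cultures.

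The values are log2 intensities that the authors made with the robust multi-array average (RMA) in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays and summarises the probes of each probe set into a single deposited log2 value. The log2 scale was read from the values, which lay between 3.18 and 14.6, with array medians from 7.19 to 7.26. Quantile normalisation gives all arrays nearly the same distribution, so a change shared by most transcripts would not be visible. RMA carries no detection call, and changes of dim probe sets are compressed towards 0. The genome build of the array annotation was not given in the sources used here, so no coordinates are reported. The deposited table had 0 columns of other samples.

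Of 35556 probe sets, 21789 had exactly 1 gene symbol in the platform annotation, 1621 had several symbols and 12146 had no listed gene. The Entrez IDs of 21698 of the 21789 were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and left 91 unmatched. Probe sets with several symbols or none were not named and did not enter the comparison. Of several probe sets of a gene, the brightest over the 6 arrays was kept, which left 19938 genes, 998 of them with more than 1 probe set. Members of the gene lists were matched by symbol, and an older symbol was replaced only where it was no gene's current symbol and a synonym of 1 gene alone. Oct6, Sc4mol, Pkm2, Tex13 and Ero1l were replaced by Pou3f1, Msmo1, Pkm, Tex13b and Ero1a in this way.

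Tamoxifen-treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with no filter on dim genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 changes are limma's standard errors (SE), and errors of group means are standard deviations (SD). Gene lists were tested with limma's camera at the preset inter-gene correlation of 0.01. The adjusted p of a list covers 27 lists, each with at least 5 measured members. Camera was repeated with a correlation estimated for each list. In that form its p rests on the residual degrees of freedom of 6 arrays, which are few. Small p-values are hard to reach there, so a lost call does not by itself show that a list was unchanged. The rotation test fry was also run; its directional p asks whether the genes of a list move, on balance, in 1 direction. As a description, the median change of a list was set against 10000 random lists matched on signal in 50 bins.

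The named genes follow a fixed rule. It takes Dicer1, and the 12 largest rises and 12 largest falls among called genes whose 3 tamoxifen values all lay on the same side of the 3 untreated values; placeholder symbols and microRNA genes were left out. It adds from each list up to 2 called members per direction, or the 2 with the smallest p where no member was called. Genes outside the rule are said to be so. The rule gave 78 genes, 66 of them called.

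The replicate numbers were checked for pairing before the calls were compared. Deviations from the group means of same-numbered arrays correlated across genes at 0.356, 0.345 and 0.389 for numbers 1, 2 and 3. Each of the 6 arrays correlated best with the array of its own number in the other group. The numbers were therefore taken to pair the samples, and a fit with the replicate number as a block was run beside the unblocked one.

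The code was tested on simulated arrays with the spread of the real ones and 19938 genes, 200 of them changed. It recovered 66% of genes changed by 0.5 on the log2 scale and 93% of those changed by 1, with a median ratio of estimated to true change of 0.994. It called 9 unchanged genes. Of 50 simulated lists without a shift, 0 were called by camera, and a list shifted by 0.2 had an adjusted p of 4.08e-13. Genes in the simulation were independent, so it says nothing of lists whose members swing together. The number of arrays limits the precision of all values.

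Alternatives were the replicate block, the mean of a gene's probe sets, leaving out the dimmest 40% of genes, median centring, renewed quantile normalisation, a variance prior with trend and robust estimation, array weights, all probe sets, 2 stricter thresholds, and leaving out each array. Cyclic loess normalisation and a fit to all probe sets with a listed gene were added after the data were seen. A test of microRNA seed sites was planned and not run, since sequences of 3' untranslated regions were not used here.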

Results

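Gene expression was measured in mouse embryonic stem cells whose Dicer alleles are flanked by recombination sites, before and after Dicer deletion. Dicer is the ribonuclease that cuts hairpin precursors into mature microRNAs. Tamoxifen served to induce the deletion, and treated cells were collected on day 5, after 3 days with tamoxifen and 2 days without. No collection day was recorded for the untreated cells. Each group had 3 arrays. The comparison asks which transcripts differ once Dicer has been removed. Arrays of the same group correlated at 0.996 to 0.998 across genes and arrays of different groups at 0.993 to 0.996. The first principal component held 52.7% of the variance and separated the groups. Tamoxifen replicate 1 lay closest to the untreated arrays on it, at 6.87 against 17.9 and 15.8 for the other tamoxifen arrays. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Wild-type cells given tamoxifen were not analysed here, so the changes belong to tamoxifen and Dicer deletion together. Any difference in days in culture between the groups would also enter them.

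The targeted gene was the most clearly changed of the 19938 genes. Dicer1 (probe set 10402444) fell from 11.42 ± 0.06 in untreated cells to 9.57 ± 0.11 after tamoxifen (log2, SD, n = 3). This is a log2 change of -1.85 ± 0.07 (SE), or 3.62-fold, with a limma adjusted p of 3.61e-05, and it ranked 1 both by p and by size of fall. The signal that remained was 27.7% of the untreated level, with a 95% confidence interval from 24.6% to 31.1%. All 3 tamoxifen arrays lay below all 3 untreated arrays, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The deleted exons are not stated in the labels, so the probe set may also read parts of the transcript that were not deleted.

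**Figure D1:**
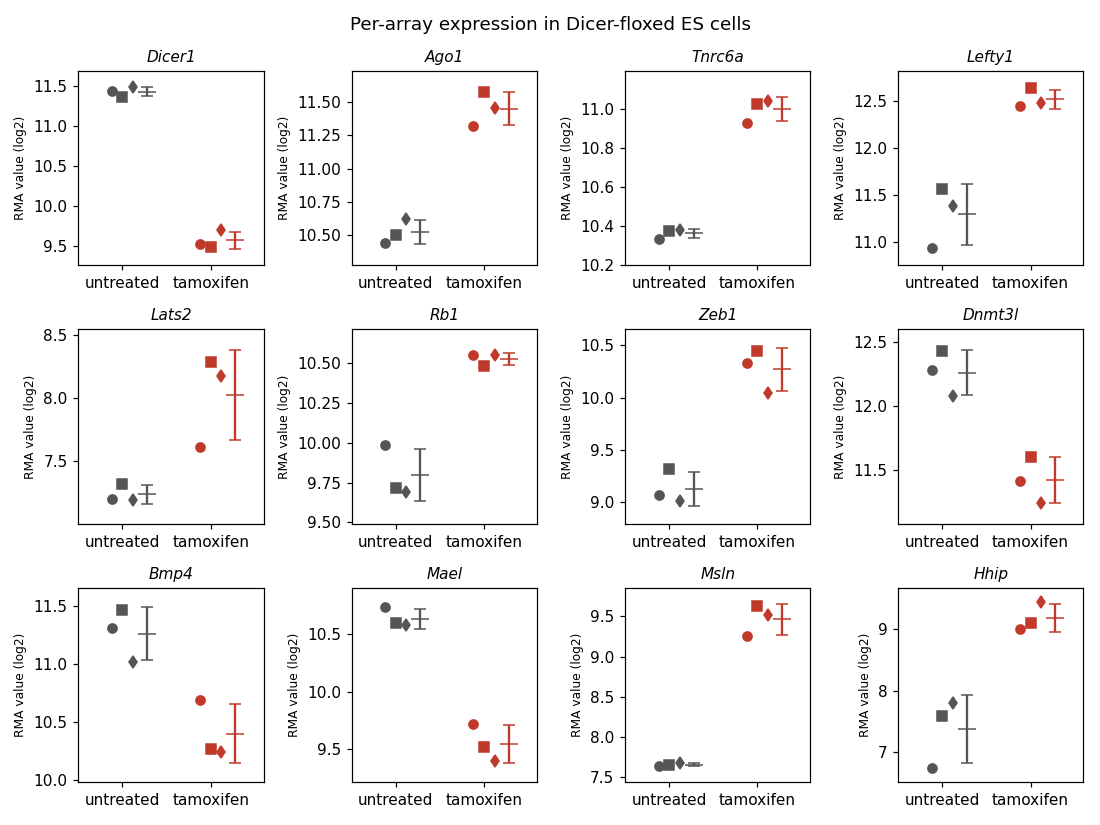
Log2 RMA values of 12 genes on each array, untreated in grey and tamoxifen in red; circle, square and diamond are replicates 1, 2 and 3, and the bars show mean ± SD (n = 3), with a separate vertical range for each gene. Dicer1 lay near 11.42 in untreated cells and 9.57 after tamoxifen, and the groups did not overlap for any of the 12 genes.

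After tamoxifen 756 genes rose and 796 fell, 1552 called genes in all. At an unadjusted limma p under 0.05 there were 4885 of the 19938 genes. Counts at that p in the lists below are to be set beside this share. Every list with no called member had a smaller share. Hhip, which binds hedgehog ligands, rose 3.51-fold (log2 1.81 ± 0.24, adjusted p = 0.0061), and Msln, which encodes the surface protein mesothelin, rose 3.5-fold (log2 1.81 ± 0.09, adjusted p = 0.000165). Tgfbi, an extracellular matrix protein induced by TGF-beta, rose by 1.49 ± 0.13 on the log2 scale, and Igfbp7, which binds insulin-like growth factors, by 1.24 ± 0.09. The Nodal inhibitor Lefty1 rose by 1.23 ± 0.14, the complement inhibitor Serping1 by 1.18 ± 0.09 and the heparan sulfate sulfatase Sulf1 by 1.18 ± 0.17. Ankrd52, a subunit of the protein phosphatase that acts on Argonaute proteins, rose by 1.21 ± 0.08. The other largest rises were in Sh3rf2, Samd9l, Dusp27 and the imprinted zinc-finger gene Plagl1, at 1.17 to 1.32. Adjusted p-values of these 12 genes ran from 0.000165 to 0.0164.

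After Dicer1, the largest falls were in Zfy1, a Y-linked zinc-finger gene, at -1.26 ± 0.17 (adjusted p = 0.00664), and Mal2, a membrane protein of apical transport, at -1.25 ± 0.12 (adjusted p = 0.0017). Mael, a germ-cell gene of the piRNA pathway, fell by 1.09 ± 0.09 on the log2 scale. Ddit4, an inhibitor of mTORC1, fell by 0.92 ± 0.14, and Fah, an enzyme of tyrosine breakdown, by 0.98 ± 0.11. C1qtnf12, Ppm1j, Pstpip2, Elavl3, Kdelr3 and Plac8 changed by -1.02 to -0.90. Of the falls, those of C1qtnf12 (adjusted p = 0.0484), Elavl3 (0.029) and Kdelr3 (0.0411) were past the threshold in only 2, 3 and 1 of the 6 fits that each left out 1 array. C1qtnf12 was also not called after cyclic loess (0.0565). Samd9l among the rises passed in 5 and the other top genes in all 6.

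With the replicate number as a block, 3472 genes were called (1570 higher, 1902 lower), among them all 1552. Single arrays moved the count: it was 516 without untreated replicate 2, 908 without untreated replicate 3, 355 without tamoxifen replicate 2 and 539 without tamoxifen replicate 3. Of the 66 called genes named by the rule, 33 stayed past the threshold whichever array was left out. The number lost was 14, 19 and 20 without untreated replicates 1, 2 and 3, and 8, 31 and 24 without tamoxifen replicates 1, 2 and 3. The fit over all 35556 probe sets took in 12146 with no listed gene, among which array controls could not be told apart. It called 336 probe sets, against 1657 in the fit to all probe sets with a listed gene. In the fit over all probe sets 39 of the 66 lost their call, with adjusted p-values from 0.05 to 0.149. Among the largest changes these were Sh3rf2 (0.0559), Samd9l (0.0813), Sulf1 (0.0518), Dusp27 (0.0544), Plagl1 (0.0592), C1qtnf12 (0.149), Elavl3 (0.108), Kdelr3 (0.133) and Ddit4 (0.0548). Of the named genes in the lists below, only Lefty1, Mael, Ago1, Tnrc6a, Rb1, Ei24, Gdf3, Dnmt3l, Nodal, Id1, Id2, Zeb1, Ncam1 and Fgfr2 kept theirs beside Dicer1. The change also moved slightly with signal: over 10 equal bins of genes by mean signal, its median ran from 0.06 in the fourth bin to -0.06 in the seventh.

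Other genes of the small RNA pathway changed beside Dicer1. Of 18 measured members, Ago1, Tnrc6a and Tnrc6b rose, Dicer1 fell and 14 were not called. Ago1, an Argonaute protein that carries microRNAs, rose 1.90-fold (log2 0.93 ± 0.08, adjusted p = 0.00129). Tnrc6a, a partner of Argonaute in silencing, rose by 0.64 ± 0.06 on the log2 scale (adjusted p = 0.0017), and its relative Tnrc6b, outside the naming rule, by 0.51 ± 0.06 (adjusted p = 0.00499). Adjusted over the list alone, 6 members rose and 1 fell. As a list the group was not called by camera (median 0.09, adjusted p = 0.0738); it passed without untreated replicate 3 (0.012), without tamoxifen replicate 1 (0.0457) and after cyclic loess (0.0214). With an estimated correlation the adjusted p was 0.529, and 0.475 after loess. Without 1 array the median ran from 0.02 to 0.13, being lowest without untreated replicate 1 (adjusted p = 0.247). The list also passed without the dimmest genes (0.0483), after renewed quantile normalisation (0.0235) and over all probe sets (0.0282).

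Genes described as targets of the miR-290 family, the main microRNAs of mouse embryonic stem cells, rose as a list. Of 23 measured members, 8 rose, 0 fell and 15 were not called; at an unadjusted p under 0.05, 14 were higher and 2 lower. Adjusted over the list alone, 13 rose and 1 fell, and with the replicate block 11 rose and 1 fell. Lefty1 was the largest rise. Lats2, a kinase of the Hippo pathway, rose by 0.78 ± 0.15 on the log2 scale (adjusted p = 0.0199, called in 2 of 6 fits without 1 array), and the retinoblastoma gene Rb1 by 0.73 ± 0.09 (adjusted p = 0.00389). Ei24 and the methyl-CpG-binding protein Mbd2 rose by 0.48 ± 0.07 and 0.37 ± 0.07; Mbd2 was called in 3 of 6 fits without 1 array. The median change was 0.19, above the 95% range of signal-matched random lists, -0.11 to 0.06. Camera gave an adjusted p of 0.00012, and adjusted p = 0.197 with an estimated correlation; fry gave 0.00331, and 0.051 with the replicate block. The list was called in 6 of 6 fits without 1 array, and its median was higher in 3 of 3 replicate pairs. Regrouping the 6 arrays without regard to treatment called it in 2 of 9 regroupings, with a lowest camera adjusted p of 0.00827. Each regrouping sets 2 arrays of 1 treatment and 1 of the other against the reverse, so it keeps part of the tamoxifen difference. Calls in regroupings, here and below, are therefore no rate of false calls.

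Among 22 measured let-7 targets, 5 rose and 0 fell, with 6 higher and 4 lower at an unadjusted p under 0.05, and 6 rose and 2 fell adjusted over the list alone. With the replicate block 6 rose and 3 fell. The cyclin Ccnd1 rose by 0.56 ± 0.10 on the log2 scale (adjusted p = 0.0158, called in 4 of 6 fits without 1 array) and the chromatin protein Hmga2 by 0.49 ± 0.11 (adjusted p = 0.0329, called in 1 of 6). The list was not called by camera (median 0.09, adjusted p = 0.107), but passed after cyclic loess (0.0283) and without tamoxifen replicate 1 (0.0411). With an estimated correlation the adjusted p was 0.468, and 0.465 after loess. It also passed after renewed quantile normalisation (0.0325). None of the 10 measured microRNA host transcripts was called by limma, 2 being higher at an unadjusted p under 0.05. The smallest p-values were those of Mir670hg (0.19 ± 0.06) and Nfyc (0.27 ± 0.11, adjusted p = 0.178, or 0.0285 with the block). Camera's adjusted p for these hosts was 0.168.

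Naive pluripotency genes did not shift as a list (26 measured, 3 rose, 0 fell, median 0.00, adjusted p = 0.838); adjusted over the list alone, 5 rose and 4 fell. The transcription factor Klf2 rose by 0.58 ± 0.09 on the log2 scale (adjusted p = 0.00903) and the growth factor Gdf3 by 0.55 ± 0.08 (adjusted p = 0.00824). With the block, 3 members rose and 3 fell. The core factors Pou5f1, Sox2 and Nanog, picked after their values were seen, had changes of -0.11 ± 0.07, 0.06 ± 0.06 and 0.07 ± 0.06 with adjusted p-values of 0.396, 0.597 and 0.52. Of 29 listed genes of the 2-cell-like state 14 were measured, and the Zscan4 genes and Dux were not among them. No measured gene was called, 3 were higher at an unadjusted p under 0.05, and camera's adjusted p was 0.17. These values do not cover the listed genes that were not measured. Usp17ld and Usp17lc had values of 0.41 ± 0.11 (adjusted p = 0.0578) and 0.30 ± 0.10 (0.113), which passed with the block (0.0185 and 0.0355).

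Among 15 members of the DNA methylation machinery, 2 rose and 1 fell, or 2 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.74). With the replicate block 2 rose and 3 fell. Dnmt3l, the cofactor of the de novo methyltransferases, fell by 0.84 ± 0.11 on the log2 scale, 1.79-fold, with an adjusted p of 0.00616, and was called whichever array was left out. The methylcytosine oxidase Tet3 rose by 0.44 ± 0.11 (adjusted p = 0.0485), called in 1 of 6 fits without 1 array and not after cyclic loess (0.0581); its other probe set changed by 0.27. Of 28 Polycomb genes 0 were called by limma (2 higher and 1 lower at an unadjusted p under 0.05; list adjusted p = 0.838). Bmi1 had a value of 0.42 ± 0.12 (adjusted p = 0.0701, or 0.0205 with the block), and Phc3 of 0.25 ± 0.08 (adjusted p = 0.0866), with 0.52 for its other probe set.

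Nodal and BMP signalling genes were called as a list, with members on both sides. Of 23 measured, 8 rose and 2 fell, or 11 and 5 adjusted over the list alone and 9 and 4 with the replicate block. Lefty1 and Nodal, the ligand that Lefty1 inhibits, both rose, Nodal by 0.42 ± 0.06 on the log2 scale (adjusted p = 0.00664). On the BMP side, the ligand Bmp4 fell 1.81-fold (log2 -0.86 ± 0.14, adjusted p = 0.0122, called in 5 of 6 fits without 1 array) and its target Id1 by 0.61 ± 0.08 (adjusted p = 0.00527), while another member of the Id family, Id2, rose by 0.78 ± 0.10 (adjusted p = 0.00456). The median was 0.16. Camera gave an adjusted p of 0.0253, and adjusted p = 0.416 with an estimated correlation; without untreated replicate 3 the adjusted p was 0.0519. The median was 0.10 to 0.20 when 1 array was left out. Fry gave 0.0371, and 0.123 with the replicate block. In regroupings the list was called in 1 of 9 (adjusted p = 0.0429).

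The epithelial and mesenchymal genes moved in both directions and were not called as a list (20 measured, 2 rose, 3 fell, adjusted p = 0.777). Adjusted over the list alone, 3 rose and 5 fell. Zeb1, a repressor of epithelial genes, rose 2.21-fold (log2 1.14 ± 0.12, adjusted p = 0.00225), and Zeb2 by 0.51 ± 0.09 (adjusted p = 0.0135). The tight junction gene Cldn6 fell by 0.58 ± 0.10 (adjusted p = 0.0148) and the epithelial splicing regulator Esrp1 by 0.48 ± 0.10 (adjusted p = 0.0285). Zeb1 was called whichever array was left out; Zeb2, Cldn6 and Esrp1 were called in 4, 5 and 2 of the 6 fits.

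Metabolic gene lists were lower. Of 17 measured glycolysis genes 0 rose and 2 fell, with 3 falling adjusted over the list alone and 9 with the block. Hexokinase Hk2 fell by 0.41 ± 0.10 on the log2 scale (adjusted p = 0.0397) and the lactate transporter Slc16a1 by 0.37 ± 0.08 (adjusted p = 0.0306); they were called in 2 and 1 of the 6 fits without 1 array, and Hk2 not after cyclic loess (0.0565). The list's median was -0.22 and lay at -0.20, -0.24 and -0.22 in the 3 replicate pairs. Camera gave an adjusted p of 0.00012, and adjusted p = 0.416 with an estimated correlation; fry did not call it (0.111, or 0.0527 with the block). Of 19 cholesterol synthesis genes 0 rose and 3 fell (3 adjusted over the list alone, 5 with the block). Cyp51 and Msmo1, which remove methyl groups from sterol precursors, fell by 0.60 ± 0.12 (adjusted p = 0.0249) and 0.56 ± 0.10 (adjusted p = 0.0137), called in 2 and 5 of the 6 fits without 1 array. The median was -0.19, with an adjusted p of 0.00012, and adjusted p = 0.416 with an estimated correlation; fry did not call it (0.0894, or 0.143 with the block). It lay at -0.34, -0.08 and -0.11 in the replicate pairs and ran from -0.25 to -0.11 when 1 array was left out, the smallest fall being without untreated replicate 1. Camera also called these lists in 5 of 9 regroupings for glycolysis and 6 of 9 for cholesterol, with adjusted p-values as low as 4.38e-07 and 9.72e-06, smaller than with the real groups.

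Camera called genes of the unfolded protein and amino acid stress responses lower as a list, but not in all settings. Of 25 measured, 1 rose and 3 fell, the same counts as adjusted over the list alone; 1 rose and 6 fell with the block. Beside Ddit4, the stress regulator Nupr1 fell by 0.58 ± 0.14 on the log2 scale (adjusted p = 0.0438), while the chaperone gene Dnajb9 rose by 0.35 ± 0.08 (adjusted p = 0.0367); both were called in 1 of 6 fits without 1 array, and Nupr1 not after cyclic loess (0.0512). The median was -0.14, with an adjusted p of 0.0141, and adjusted p = 0.468 with an estimated correlation. The call was lost without untreated replicate 2 (0.112) and without untreated replicate 3 (0.088), and the median was lower in 2 of 3 replicate pairs (0.05, -0.23 and -0.21). When 1 array was left out it ran from -0.23 without untreated replicate 1 to -0.06 without untreated replicate 2. Fry did not call the list (0.255), nor did camera without the dimmest genes (0.0844). Of 9 regroupings 3 called it, with an adjusted p as low as 1.79e-09.

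Camera called germline genes lower as a list, with Mael in the lead. Of 27 measured, 0 rose and 2 fell, with 2 rising and 11 falling adjusted over the list alone, and 2 and 11 with the block. Slc25a31, a mitochondrial carrier of germ cells, fell by 0.47 ± 0.10 on the log2 scale (adjusted p = 0.0236, called in 2 of 6 fits without 1 array). The median was -0.16, below the 95% range of matched lists, -0.04 to 0.08, and was lower in 3 of 3 pairs. Camera gave an adjusted p of 0.00325, and adjusted p = 0.416 with an estimated correlation; fry gave 0.0371, and 0.114 with the replicate block. Without the dimmest genes the median was -0.34 and the list was not called (0.0715). Of 9 regroupings 3 called it, the lowest adjusted p being 0.00258.

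Several lineage lists were higher by small amounts. In the primed epiblast list only Nodal rose among 19 measured in the unblocked fit (1 adjusted over the list alone). With the block 3 rose and 1 fell, and after cyclic loess 3 rose and 0 fell. The list's median was 0.12, with a camera adjusted p of 0.0463, and adjusted p = 0.468 with an estimated correlation. With the block the adjusted p was 0.0583, and it was 0.138, 0.0927, 0.182 and 0.104 without untreated replicate 1, untreated replicate 3, tamoxifen replicate 2 and tamoxifen replicate 3. Over the 6 fits without 1 array its median ran from 0.05 to 0.19. With array weights the adjusted p was 0.0714 and fry gave 0.253; 4 of 9 regroupings called the list, with an adjusted p as low as 6.8e-06. Among 20 neuroectoderm genes 2 rose and 0 fell, also adjusted over the list alone. The neurogenic factor Neurod1 rose by 0.91 ± 0.18 on the log2 scale (adjusted p = 0.0194, called in 3 of 6 fits without 1 array), and the adhesion molecule Ncam1 by 0.55 ± 0.08 (adjusted p = 0.00874). The list's median was 0.09, with an adjusted p of 0.0313, and adjusted p = 0.416 with an estimated correlation; it was 0.0927 without untreated replicate 3 and 0.102 without tamoxifen replicate 2, and the median ran from 0.06 to 0.14 over the fits without 1 array. It was 0.0715 without the dimmest genes and 0.132 with fry, and 3 of 9 regroupings called the list (lowest adjusted p = 0.0229). Among 37 Hox genes 0 were called by limma and 4 were higher at an unadjusted p under 0.05, a smaller share than over all genes. Hoxd13 and Hoxc8 had values of 0.25 ± 0.08 (adjusted p = 0.0981, or 0.0232 with the block) and 0.28 ± 0.09 (0.107). The median was 0.08, with an adjusted p of 0.0165, and adjusted p = 0.432 with an estimated correlation; it was 0.088 without untreated replicate 3, 0.054 without tamoxifen replicate 2, 0.196 after cyclic loess, 0.253 after renewed quantile normalisation and 0.111 with fry. In regroupings 1 of 9 called it (0.000225).

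Markers of fibroblasts, which can serve as feeder cells, moved with these lists. None of 23 was called by limma, 3 being higher and 1 lower at an unadjusted p under 0.05. The median was 0.09, with an adjusted p of 0.0253, and adjusted p = 0.468 with an estimated correlation; it was 0.0927 without untreated replicate 3, 0.0599 without tamoxifen replicate 2, 0.0855 without tamoxifen replicate 3, 0.0769 after cyclic loess, 0.0761 after renewed quantile normalisation, 0.0808 without the dimmest genes and 0.176 with fry. Of 9 regroupings 2 called it, with an adjusted p as low as 1.41e-05. The median ran from 0.08 to 0.14 when 1 array was left out and was higher in 2 of 3 replicate pairs. The 5 brightest markers changed by 0.04 ± 0.10 on average (standard error over the 5 genes, not over arrays). Lox had a value of 0.24 ± 0.07 (adjusted p = 0.0608, or 0.0378 with the block) and Thy1 of -0.32 ± 0.11 (adjusted p = 0.0985, or 0.00725 with the block).

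Camera called no other lineage list over all 6 arrays. Among 19 mesoderm and primitive streak genes 2 rose (5 adjusted over the list alone and 5 with the block, where 1 fell). These were Gsc, at 0.32 ± 0.08 (adjusted p = 0.042, called in 2 of 6 fits without 1 array), and the growth factor receptor Kdr, at 0.26 ± 0.07 (adjusted p = 0.0468); the list had an adjusted p of 0.0738, or 0.0457 without tamoxifen replicate 1. Kdr was called in 0 of the 6 fits without 1 array and not after cyclic loess (0.0602). Among 20 endoderm genes the laminin gene Lamc1 rose by 0.35 ± 0.06 (adjusted p = 0.0126, called in 4 of 6 such fits); the list had an adjusted p of 0.378, or 0.0364 without untreated replicate 1. Among 18 trophectoderm genes Id2 and the receptor Fgfr2 rose, the latter by 0.87 ± 0.11 (adjusted p = 0.00499); the list had a camera adjusted p of 0.0776, or 0.0457 without tamoxifen replicate 1. Fry called it at 0.0371, but not with the replicate block (0.152). Adjusted over the list alone, 1 endoderm and 2 trophectoderm genes rose. With the replicate block 2 endoderm genes rose and 2 fell, and 3 trophectoderm genes rose and 3 fell. Without 1 array the medians ran from 0.05 to 0.11 for mesoderm, 0.01 to 0.12 for endoderm and 0.06 to 0.14 for trophectoderm.

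Camera called neither the cell cycle lists nor the p53 targets over all 6 arrays. Cdkn1a, listed as a cell cycle inhibitor, p53 target and miR-290 family target, was not among the measured genes, nor was the p53 target Bax. The list results do not cover them. Of 30 cell cycle drivers 3 rose and 2 fell, or 4 and 6 adjusted over the list alone, with 4 higher and 9 lower at an unadjusted p under 0.05. The list's median was -0.10, at percentile 1.1 of matched lists. Camera gave an adjusted p of 0.113, and fry 0.0371, or 0.143 with the replicate block. Ccnd1 and the cyclin Ccne2 rose, Ccne2 by 0.39 ± 0.08 on the log2 scale (adjusted p = 0.0264). The transcription factor E2f2 fell by 0.48 ± 0.10 (adjusted p = 0.0224) and the phosphatase Cdc25c by 0.32 ± 0.08 (adjusted p = 0.0368, and 0.0602 after cyclic loess). Ccne2, E2f2 and Cdc25c were called in 2, 3 and 1 of the 6 fits without 1 array. Of 16 cell cycle inhibitors 3 rose, Lats2 and Rb1 among them, and Gadd45a fell by 0.46 ± 0.11 (adjusted p = 0.0408, and 0.052 after cyclic loess; called in 1 of 6 fits without 1 array); the list had an adjusted p of 0.201, with 4 rising and 1 falling adjusted over the list alone. Of 23 p53 targets 3 rose, with Ei24 and Perp (0.42 ± 0.09, adjusted p = 0.0263, called in 2 of 6) in the lead, and Ddit4 fell. Adjusted over that list alone, 4 rose and 1 fell, and the list had an adjusted p of 0.168, or 0.0355 without tamoxifen replicate 1; its median ran from 0.03 to 0.13 without 1 array.

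Of 25 interferon response genes 3 rose and 1 fell, also adjusted over the list alone, or 6 and 2 with the block. Oas2, an antiviral RNA sensor, rose by 0.57 ± 0.12 on the log2 scale (adjusted p = 0.0255) and Irf9 by 0.40 ± 0.07 (adjusted p = 0.0135), whereas Stat2, the partner of Irf9, fell by 0.50 ± 0.12 (adjusted p = 0.0422, and 0.0582 after cyclic loess). They were called in 3, 4 and 2 of the 6 fits without 1 array. The list was not called by camera (adjusted p = 0.0695); fry gave 0.0371, and 0.0541 with the block. Of 22 imprinted genes 3 rose and 0 fell, also adjusted over the list alone, Plagl1 first and Ndn by 0.42 ± 0.08 (adjusted p = 0.0197, called in 3 of 6 fits). The list had a camera adjusted p of 0.104, or 0.0438 without tamoxifen replicate 1; fry gave 0.0371, and 0.123 with the block. Of 60 ribosomal protein genes 0 were called by limma (1 higher and 5 lower at an unadjusted p under 0.05) and 4 fell with the block. The smallest p-values were those of Rpl10l, at -0.36 ± 0.09 (adjusted p = 0.0515, or 0.023 with the block), and Rpl34, at -0.22 ± 0.06 (0.0552, or 0.0376 with the block). The ribosomal list had an adjusted p of 0.168, or 0.0438 without tamoxifen replicate 1.

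**Figure D2:**
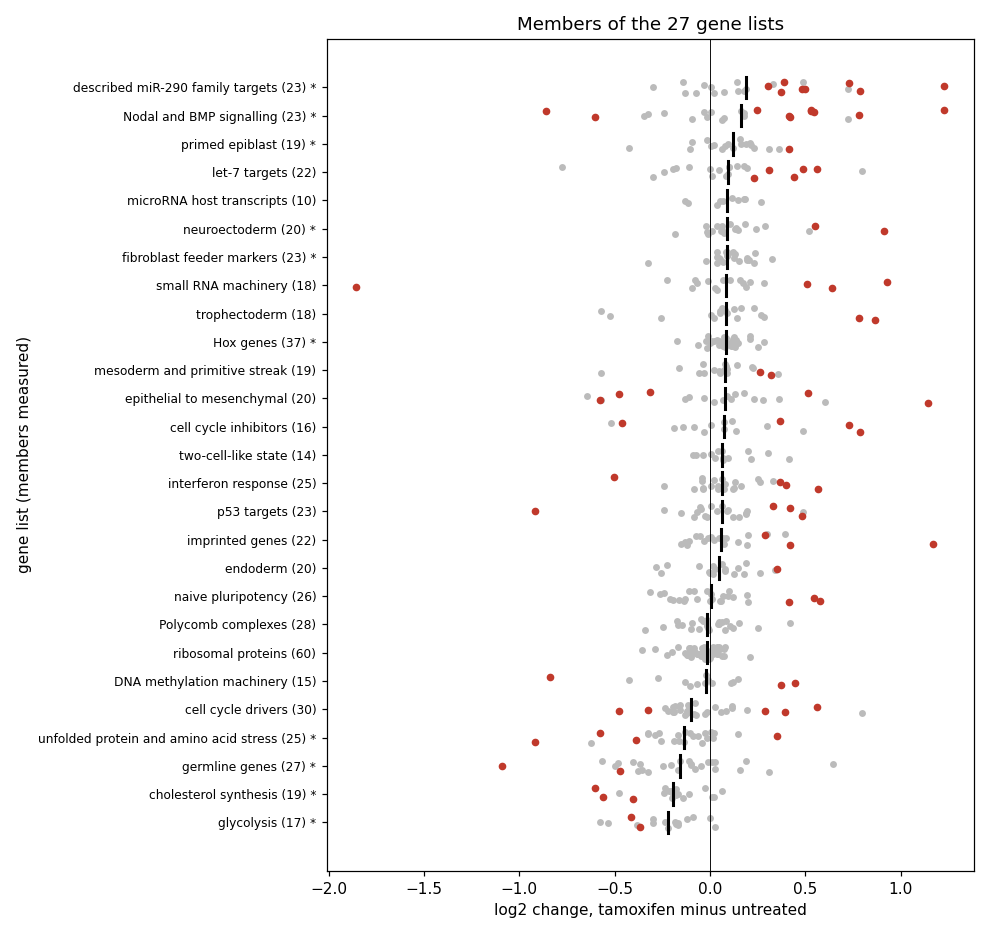
Log2 change after tamoxifen of the measured members of the 27 gene lists, ordered by median; red points are called genes, grey points are not, black bars are medians and asterisks mark the 10 lists called by camera at the preset correlation. Medians ran from -0.22 for glycolysis to 0.19 for described miR-290 family targets.

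In all, camera called 10 of the 27 lists at the preset correlation and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. With an estimated correlation 0 were also called with the replicate block (lowest adjusted p = 0.571) and after cyclic loess (0.303). Few residual degrees of freedom, fewest with the block, limit that form of camera. Its lack of calls therefore does not show that the lists were unchanged, and it gives them no backing either. Fry called 3 of these 10 lists (miR-290 targets, Nodal and BMP, germline) and lost 7; it also called 4 that camera did not. With the replicate block fry called 0 lists, and 9 had an unadjusted p under 0.05. At the preset correlation, regroupings of the 6 arrays that mixed treated and untreated samples called 2 to 11 lists. Each of the 10 lists was called in at least 1 of them, and 8 of the 10 with a lower adjusted p than with the real groups. Every regrouping keeps part of the tamoxifen difference, and most keep a replicate pair on 1 side. These counts are therefore no rate of false calls.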

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

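The tests of signal shift in the Hox, fibroblast, neuroectoderm and metabolic lists, those of hypoxia and of swings between cultures, and that of tamoxifen apart from Dicer loss were chosen only after the result was seen. Signals outside the comparison came from probe sets that could not be given 1 gene. In a limma fit over all 35556 probe sets, 9 of 1621 probe sets with several gene symbols were called, 9 higher and 0 lower, with a largest change of 0.94 ± 0.07 (SE, adjusted p = 0.0123). Of 12146 probe sets with no listed gene 38 were called, 25 higher and 13 lower, with a largest change of 1.28 ± 0.08 (adjusted p = 0.00798). In the same fit 289 of 21789 probe sets with 1 symbol were called.

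The 6 arrays can be split into 2 groups of 3 in 10 ways. Only 1 of the 10, the real one, gave 1552 genes; the highest count of the others was 0, with up to 1418 genes at an unadjusted p under 0.05. For the lists, 3 of the 10 splits called at least the 10 of the real one, and the highest of the others was 11, from a split that parts all 3 replicate pairs as the real one does. The other 2 splits that part all pairs called 3 and 2 lists. All other splits mix the treatments, so they keep part of the tamoxifen difference between their groups and put the rest into the spread within them. Low gene counts there are thus nearly fixed in advance once the treatments differ, and list calls there are no rate of false calls. With so few splits no share under 0.05 can be reached.

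The Hox, fibroblast and neuroectoderm lists were higher after tamoxifen by medians of 0.08, 0.09 and 0.09 with few or no called members. A shift of change with signal between arrays is a candidate explanation. The Hox median lay at percentile 94.4 of signal-matched random lists and the fibroblast median at percentile 95.8. Neither list was called by camera after cyclic loess (adjusted p = 0.196 and 0.0769). The Hox median went from 0.082 to 0.041 with loess, so the shift may account for part of it. The fibroblast median went only from 0.089 to 0.083, so loess ended the call with little of the change. The shift is left open for the fibroblast list. The neuroectoderm median went only from 0.089 to 0.082 with loess, and its list was still called by camera (adjusted p = 0.0364). At the preset correlation this argues against the shift as the whole cause for that list. With an estimated correlation the list was not called after loess (adjusted p = 0.465). Its median before loess lay at percentile 96.2 of matched lists, so a part played by the shift is left open. More feeder cells in the tamoxifen cultures cannot be excluded either. The 5 brightest markers, Mmp2, Thy1, Col1a1, Col6a2 and Col5a1, changed by 0.0423 ± 0.0959 on average, against 0.0893 for the list. This error is a standard error over the 5 genes and not limma's, and it holds no spread between arrays. Thy1 alone of the 5 was lower (-0.324). The comparison therefore does not decide it.

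The glycolysis and cholesterol lists were lower, with medians of -0.22 and -0.19. The signal shift alone is argued against at the preset correlation, where both stayed called after cyclic loess with a larger adjusted p of 0.00316; with an estimated correlation neither was called after loess (adjusted p = 0.465 and 0.475). Swings of these genes between cultures remain open. Of the 9 other splits 5 called both lists and 2 gave a smaller camera adjusted p for either. Each of these splits keeps part of the tamoxifen difference, so their calls do not decide it. Both groups hold every replicate number, so a swing shared by a pair cancels in the change between the groups. The fit with the replicate block therefore does not test it. Camera with that block gave adjusted p = 2.69e-06 and 9.21e-05, or 0.571 and 0.603 with an estimated correlation. In all 3 pairs 15 of 17 glycolysis and 15 of 19 cholesterol genes were lower. Swings not shared by a pair are left open. A weaker hypoxia response in the tamoxifen cultures may be part of it. A set of 15 hypoxia genes not looked at before had a median change of -0.187, at percentile 0.04 of matched lists. Its median was -0.33, -0.18 and -0.08 in the 3 pairs. Glycolysis lay at -0.20, -0.24 and -0.22 there, and cholesterol at -0.338, -0.0788 and -0.115. The glycolysis median thus did not follow the size of the hypoxia fall over the pairs, but members of the list differed. Falls shrank from pair 1 to pair 3 in some, such as Aldoc (-0.756, -0.588 and -0.386) and Slc16a3 (-0.699, -0.527 and -0.374). They grew in others, such as Hk2 (-0.378, -0.4 and -0.459) and Pfkp (-0.159, -0.364 and -0.38). The pairs therefore do not decide whether the falls go together. The camera p of the 15 hypoxia genes was 0.00157, but p = 0.222 with an estimated correlation, so a weaker hypoxia response stays a hypothesis. Tamoxifen acting apart from Dicer loss cannot be told apart from the deletion, as 0 arrays of treated cells without floxed Dicer were analysed here.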

How the results depend on the processing

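Cyclic loess, the fit to all probe sets with a listed gene and fry with the replicate block were chosen after the data were seen; the other alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Dicer1 kept its direction and its call in all 15 alternatives, with log2 changes from -1.92 to -1.81 and adjusted p-values from 5.36e-06 to 0.00299. The seed-site test and its alternatives were not run. No alternative gave the Hox or 2-cell-like list a value without the dimmest 40% of genes, since fewer than 5 members were left.

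The 1552 called genes (756 higher, 796 lower) became 3472 (1570 and 1902) with the replicate block and 2511 (1393 lower) with array weights. Over all probe sets 336 were called (221 and 115), and the prior degrees of freedom of the variance fell from 4.75 to 2.67 there. All probe sets with a listed gene gave 1657 (804 and 853) and 4.42 prior degrees of freedom. The drop thus came with the 12146 probe sets without a listed gene. Stricter thresholds call fewer genes by construction: 275 (174 and 101) at 1.5-fold or more and 276 (179 and 97) at an adjusted p under 0.01. Leaving out 1 array gave 355 to 1580 genes, 221 to 686 higher and 134 to 894 lower; the low counts were 355, 539, 516 and 908 without tamoxifen replicates 2 and 3 and untreated replicates 2 and 3. The remaining alternatives gave 1509 to 1724. Of the calls 48.7% were rises, against 56.8% after cyclic loess and 45.2% with the block. Cyclic loess shared 1311 calls with the unadjusted values, 0 of them with opposite sign.

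The 10 called lists became 6 without the dimmest 40% of genes, where small RNA genes gained a call (0.0483), neuroectoderm (0.0715), stress (0.0844), fibroblast (0.0808) and germline (0.0715) lost theirs and Hox was not tested. They became 0 with an estimated correlation, and 5 to 17 when 1 array was left out (5 without untreated replicate 3, 6 without tamoxifen replicate 2, 17 without tamoxifen replicate 1). The miR-290 target, cholesterol, glycolysis and germline lists were called in 6 of 6 such fits. Beyond the counts, the block ended the call of the primed epiblast list (adjusted p = 0.0583) and brought 9 uncalled named genes past the threshold; it changed no other camera call of a list and no other call of a named gene. Of the 66 called named genes 39 were not called over all probe sets. Fry called 3 of the 10 lists and 4 others; these 7 became 0 with the block (lowest adjusted p = 0.051).

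Some lists with small medians, none of them called over all 6 arrays, turned direction; the cause was not tested. The naive pluripotency median was -0.0501 with array weights and -0.051 to 0.037 when 1 array was left out. DNA methylation genes had medians of -0.0226 without the dimmest genes, 0.0134 after renewed quantile normalisation, 0.0175 after cyclic loess and -1e-04 over all probe sets. The Polycomb values were -0.0127 both for the mean of probe sets and over all probe sets, -0.0181 without the dimmest genes, -0.000467 after quantile normalisation, 0.0115 after cyclic loess and -0.0264 to 0.0103 when 1 array was left out. Endoderm genes ranged from 0.00692 to 0.119 when 1 array was left out. The epithelial and mesenchymal list was at -0.0305 without the dimmest genes and -0.0332 to 0.11 when 1 array was left out. Where a median kept its sign, the sign of the camera test changed. Array signal over background was not given, so dim genes could not be set apart by detection.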

Other observations

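The ERK, hypoxia and microRNA-302 lists were written after the table of all genes was seen, and of the tests below those of Larp7 and of uncut hairpins were chosen only after the result was seen. Of 17 measured feedback genes of the ERK pathway, 0 rose and 6 fell, and with the replicate block 2 rose and 9 fell; falls seen in that table prompted the list, so these counts are no evidence for it. The Sprouty genes Spry1 and Spry4, which restrain receptor signalling, changed by -0.80 ± 0.07 (adjusted p = 0.00107) and -0.74 ± 0.12 (adjusted p = 0.0112) on the log2 scale. The ERK phosphatase gene Dusp4 changed by -0.78 ± 0.11, the transcription factor gene Etv4 by -0.83 ± 0.14, Ier3 by -0.71 ± 0.10 and Phlda1 by -0.31 ± 0.07. Other targets were mixed. Dusp6 had a value of -0.27 ± 0.12 (adjusted p = 0.221, or 0.0224 with the block) and Egr1 of 0.45 ± 0.12 (adjusted p = 0.0593, or 0.00601 with the block). Etv5 was at 0.09 ± 0.07, with -0.18 for its other probe set.

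Lower ERK signalling output is a hypothesis that these falls suggest. Since 6 members had prompted the list, it was tested on the 11 others. Their median was -0.0874, at percentile 10.6 of matched random lists, and their camera p was 0.43; 1 of them fell, and 2 rose and 3 fell with the block. The unseen members therefore do not decide it.

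Of 19 measured hypoxia-induced genes, 4 of which had prompted the list, 0 rose and 3 fell, which were Ddit4, Higd1a (-0.67 ± 0.08, adjusted p = 0.00354; its other probe set changed by -0.19) and the growth factor gene Vegfa (-0.55 ± 0.10, adjusted p = 0.0174). With the replicate block 10 fell. The mitophagy gene Bnip3 had a value of -0.90 ± 0.32, with an adjusted p of 0.128 without the block and 0.000233 with it, and Ndrg1 of -0.74 ± 0.23, with 0.0819 and 0.00213. Over the 15 members not looked at before, the camera p was 0.00157, or p = 0.222 with an estimated correlation, and the median was lower in 3 of 3 replicate pairs.

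Probe sets of the microRNA-302 cluster, a relative of the miR-290 family, were higher after tamoxifen although Dicer1 fell. Mir302b, Mir302c and Mir302d rose by 1.14 ± 0.24, 0.91 ± 0.23 and 0.76 ± 0.19 on the log2 scale (adjusted p = 0.0282, 0.046 and 0.0481), and Mir302a had a value of 0.53 ± 0.15 (adjusted p = 0.0723, or 0.0107 with the replicate block, where all 4 were called). All of them lay near the lower end of the array scale, with untreated means from 4.49 to 4.89. The signal shift is argued against as the whole cause, since the median of the 4 was 0.80 after cyclic loess, where however only Mir302b was still called (adjusted p = 0.0324, against 0.0562 and 0.0639 for Mir302c and Mir302d).

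All 4 microRNA-302 genes lie inside the span of the gene Larp7, which itself rose by 0.44 ± 0.08 (adjusted p = 0.0163). Larp7 minus the cluster's median was -0.390, with a standard error of 0.223 over the groups. In the 3 replicate pairs it was -0.26, -0.24 and -0.67, with a paired standard error of 0.14 and a 95% interval that reached up to 0.22. Larp7 rose less in each pair, but 3 pairs of probe sets near the lower end of the scale do not exclude signal from Larp7 transcripts, which is left open. Uncut hairpin precursors could also add signal to microRNA probe sets once Dicer is gone. The other 292 microRNA probe sets had a median change of 0.05, at percentile 100 of matched random lists (95% range 0.01 to 0.04), with 6 rising and 0 falling, or 16 and 0 with the replicate block. Their camera p was 0.00502. After cyclic loess the median was 0.02 and the camera p 0.0823. The direction is the one that uncut precursors would give; how much of the 0.83 of the microRNA-302 cluster they could account for was not tested.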
